A study of Mus musculus with 868 samples.

How the data were processed

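The deposited values are raw gene counts from the authors, 1 table per tissue, with 24421 gene symbols for each of 868 samples, and were used as deposited. The labels name bcl2fastq 2.17 for demultiplexing, TopHat2 2.1.1 for alignment to mm10 and HTSeq 0.9.1 for counting. The gene annotation, the read filters and the counting settings of these steps are not stated in the labels. All values were whole numbers and no table held a column of no sample. Of the symbols, 23376 occur in GENCODE M21, from which gene positions (mm10) were taken.

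Counts were analysed in R 4.3.3 with edgeR 4.0.16, separately in each tissue and with all its libraries in 1 fit of 18 treatment groups (36 libraries and 18 residual degrees of freedom, or 38 and 20 in brain and jejunum). Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and each contrast was tested with the quasi-likelihood F test. P values were adjusted by the Benjamini-Hochberg method within a comparison at a threshold of 0.05, and an adjusted p given without a tool is from edgeR. The standard error of a log2 fold change is its size divided by the square root of F. CPM values use TMM-scaled library sizes, except in the principal components, in the correlations of shifts between libraries and in the testis transcripts of the aripiprazole lungs.

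Before the data were examined, 18 drug and tissue pairs, 44 gene lists with 573 members, the tests, the reference and the alternatives were fixed. The reference was the mean of the 3 control groups, weighted equally, and values with it are called planned. The reference within a library set was added after the sets had been seen: Untreated and Sucrose for APAP and sofosbuvir, CMCTween for the drugs of its set, and the other 4 drugs for the set with no control. The assignment of treatments to sets rests on the expression values, not on the labels. CMCTween may hold a difference of its own from the drugs of its set, so the drug was also compared with all other groups of the set. A drug contrast with 2 libraries against 2 has 1 shared estimate of the spread from all groups of the tissue.

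Gene lists were tested with fry of limma 3.58.1 on the edgeR fit, with a directional p adjusted over the 66 planned tests of each reference, or over all 12585 list tests in the survey of every pair. Lists with fewer than 3 genes past the filter were left out. The same lists were tested with camera, at its preset correlation of 0.01 and with the estimated correlation. Members were also counted after adjusting over the list alone. The difference of a response between a pair of tissues was tested in a joint fit of both tissues over the libraries of the set. Direct differences of related drugs come from the same fits with 95% intervals from the normal distribution. The antipsychotic class was tested in a fit of a pair of groups, the libraries of the 5 drugs and those of the 3 control groups.

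Genes named as changed were chosen by a rule. Among genes past 0.05 with the same sign against each of the 3 control groups alone, with all drug libraries outside the range of the 6 control libraries on the log2 CPM scale and a mean of at least 5 CPM in the drug or the controls, the 10 (or, for short comparisons, 5) with the largest fold change in each direction may be named. After the sets had been seen, the rule was restricted to genes also past 0.05 within the set and ranked by that fold change. Symbols of the form Gm with digits or ending in Rik were counted and not named, apart from 2900060B14Rik among the 5 genes of the EMPA kidney. Members of a planned list that pass may be named, with 2 to 4 that do not. For the class and for related drugs the 5 largest in each direction may be named, in the surveys Cdkn1a, Mdm2, Prl, Gh, Slc5a2, Dbp, Per2, Arntl and Nr1d1, and for the 10 pairs with most calls 3 genes in each direction. Some genes that the rule allows are not reported here, although the counts include them. Of list members that passed, Col1a1 in skull with teriparatide (up), Srxn1 in kidney with cisplatin (up) and Gstm3 in liver with APAP (down) are given without values. Their rounded values equal constants written in the scripts, which the format does not allow, and Col1a2 was put in place of Col1a1 for this reason after its values were seen.

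Where every library of a group was at 0, the fold change is given as a bound against 3 counts over the group. With 1 to 3 counts over the group, the ratio of the counts over library sizes is given with its 95% interval (conditional binomial). These intervals and bounds hold counting error only and not the spread between mice. The first principal component was taken over treatment means of log2 CPM plus a pseudocount of 2, for genes above a mean of 20 CPM in the tissue.

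Each alternative changed 1 choice, except DESeq2, which also brought its own size factors and filtering and was run on all genes with a total count above 0, and the class within set C, which changed the drugs and the reference: Untreated alone, the vehicles alone or the mean of the other 17 groups as reference, RLE size factors, no filter beyond a total count above 0, DESeq2 1.42.0 (Wald test), only the drug and controls in the fit, the replicate number as a block, and leaving out each library of the drug and the reference in turn. Chosen after seeing the data were the set references, all other groups of the set as reference and a fit of the set alone. The tests were tried on simulated data, with the set references only after the sets had been seen. The simulated counts held no difference between sets, so they do not show how the 3 control groups perform where drug and set are mixed. Of simulated log2 changes of 1, edgeR recovered 21% in kidney and 26% in bone marrow with the 2-library set reference. With the 3 control groups it recovered 44% and 51%. In liver and brain, where the set reference is larger, it recovered 35% and 40%, against 36% and 41%. A lower count with a 2-library reference can therefore also come from lower power. With the 3 control groups as reference, the fry test missed a list raised by 0.5 log2 in liver and called it in kidney, bone marrow and brain. In brain it also called 2 lists that were not raised. The fry test was not tried on simulated data with the set references. Figures and tables used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No library was left out of the reported values. Vehicle effects beyond the control contrasts, isoforms and reads were not analysed.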

Results

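The data are 3′ mRNA counts from 24 tissues of C57BL/6N mice in 18 treatment groups, made of 15 drugs and 3 control groups. The controls were Untreated, CMCTween (0.5% carboxymethylcellulose with 0.25% Tween80) and Sucrose (5%). Every group held 2 libraries per tissue, except asenapine in brain and sofosbuvir in jejunum with 4, for 868 libraries in all. Total counts ran from 451154 to 12811780 per library (median 877592). The 48 Untreated libraries held 2875950 to 12811780, and the other 820 held 451154 to 3685250. The labels give a time for APAP (2 hours) and for EMPA (2 weeks) and a concentration for Dox (2 mg per mL). They give no other dose or time, no vehicle for any drug, and do not spell out the short names. The series title names prediction of human clinical outcomes as its purpose, and the question put to each drug here was which genes changed in the tissue it is known to act on or harm.

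The treatments fell into library sets that the labels do not mention. On the first principal component of the 18 treatment means, Untreated, Sucrose, APAP and sofosbuvir (set A, 194 libraries) lay apart from all other treatments in 23 of 24 tissues, the exception being the parotid gland. The other treatments were assigned from their profiles, after the values had been seen, to alendronate, asenapine, lurasidone, olanzapine and risedronate (set B, 242 libraries, no control group) or to CMCTween with the other 8 drugs (set C, 432 libraries). Set membership took 42.0 to 77.5% of the variance between treatment means (median 57.0%), a share that describes the sets and does not test them, since they were chosen from the same values. Sofosbuvir has 4 libraries in jejunum, and replicates 3 and 4 differed from replicates 1 and 2 along the shift between sets B and A (correlation 0.558, slope 0.749) and that between sets C and A (0.488, slope 0.595). Its count there, 1378 of its 5770 calls over 24 tissues within the set, and the totals below therefore hold libraries that do not follow set A. Of 3589 genes above 20 CPM in at least 20 tissues, 593 had a median shift of more than 2-fold between set A and the other sets, and 586 of these shifted the same way in every tissue in which they passed. Hnrnpl, an RNA-binding protein gene, was lower outside set A by a median log2 of -2.29 over 23 tissues.

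**Figure D1:**
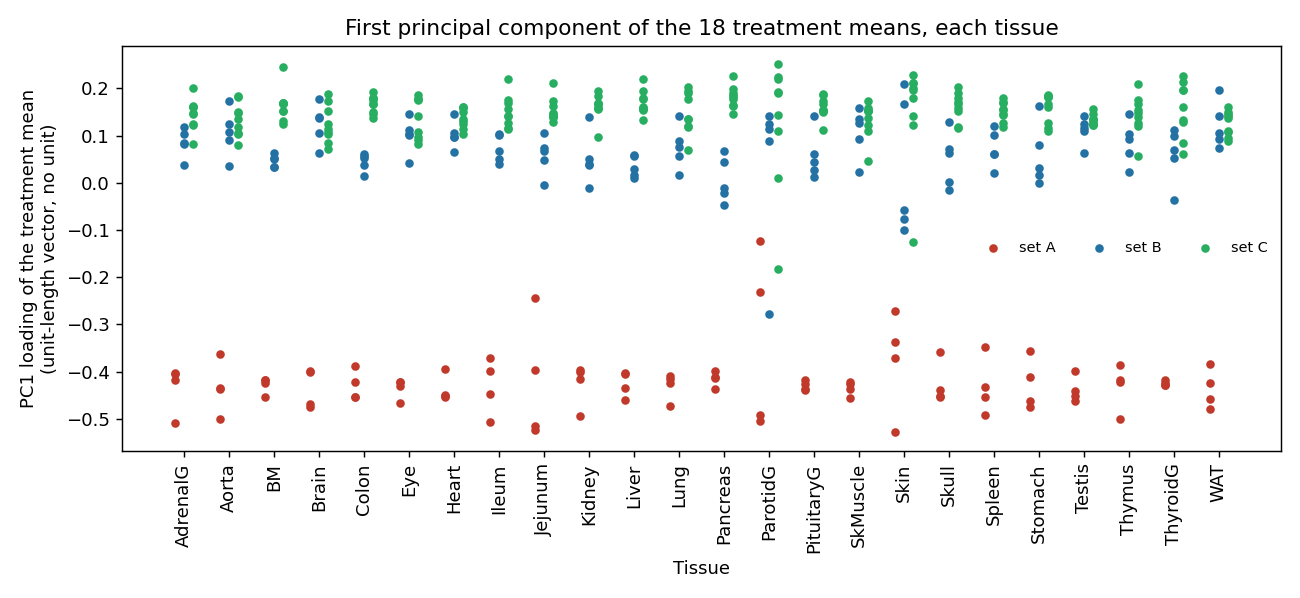
Loading of each treatment mean (unitless) on the first principal component of its tissue, for 18 treatments in 24 tissues, coloured by library set. The 4 treatments of set A lie below all others in 23 tissues, and in the parotid gland they do not.

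The control groups showed the size of this set difference. CMCTween differed from Untreated by 1606 genes in pancreas to 6278 in testis (edgeR quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05), and from Sucrose by 943 to 5363. Sucrose and Untreated, of the same set, differed by 4 genes in jejunum to 1918 in thymus, and by 1040 in liver. Their mean, used below as the reference for APAP and sofosbuvir, therefore joins groups that are not alike in liver and thymus. The jejunum counts rest on a spread that also holds the difference between the sofosbuvir libraries, which can lower them. Over the 48 vehicle and tissue pairs the vehicles gave 131035 calls against Untreated. Within set C, CMCTween differed from the mean of the 8 drugs by 774 genes in the adrenal gland, 471 in skin, 332 in ileum and 324 in eye, and by 1 to 68 in the other 20 tissues. The comparison fixed in advance, each drug against the mean of the 3 control groups, mixes the drug with the set for every drug, for those of set A through CMCTween. Each drug is therefore led below by a comparison inside its set, with the planned count beside it and planned values for some genes. The references were, for APAP and sofosbuvir, Untreated and Sucrose (4 libraries), for set C drugs CMCTween (2 libraries), and for set B drugs the other 4 drugs of the set (8 libraries, 10 in brain for a drug with 2). A set B value is thus a difference from other drugs and not from a control. The reference of each set B drug also holds drugs of its own class, so an effect they share is partly subtracted.

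**Figure D2:**
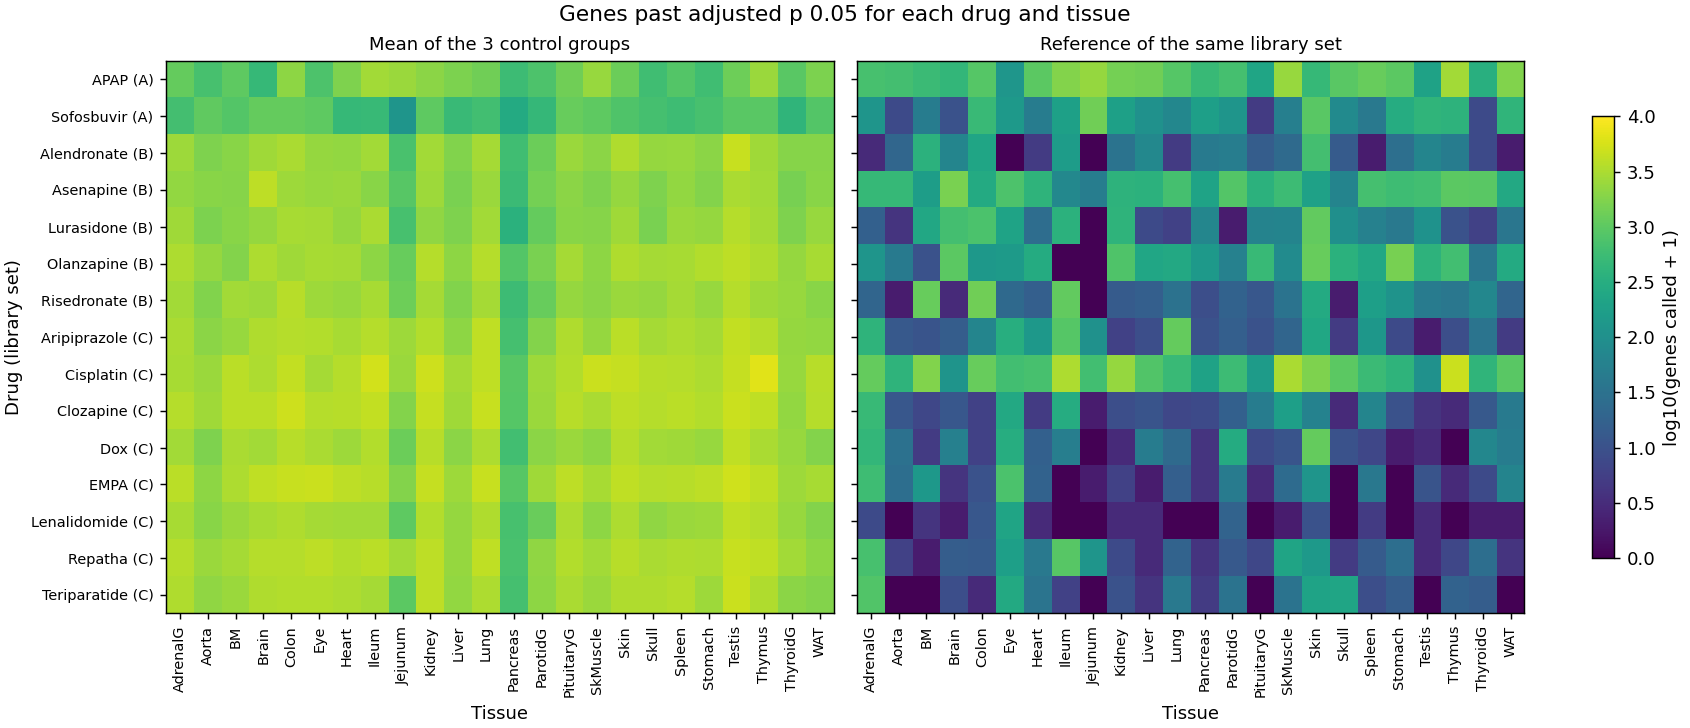
Genes past an adjusted p of 0.05 for 15 drugs (vertical axis, library set in brackets) in 24 tissues (horizontal axis), as log10 of the count plus 1. The left panel uses the mean of the 3 control groups and the right panel the reference of the same set, where 149 of 360 pairs keep at least 100 genes.

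Cisplatin, a DNA-crosslinking drug with known kidney toxicity, raised genes of tubular injury and of the p53 response in kidney and lowered genes of tubular transport. Havcr1 (KIM-1, chromosome 11, 46735080 to 46779578), the standard marker of tubular injury, rose by a log2 fold change of 7.49 ± 0.35 (SE, n = 2 against 2, adjusted p = 1.45e-29), from 2.78 to 533 CPM. The p53 target Cdkn1a (chromosome 17, 29090976 to 29100727), a cell-cycle inhibitor, rose by 6.03 ± 0.30 (adjusted p = 6.76e-13), Mdm2 by 2.84 ± 0.21 and Ccng1 by 2.70 ± 0.15. Krt20, a keratin, had 469 counts over its cisplatin libraries and 1 over the CMCTween libraries, a ratio of 466, 95% interval 83.2 to 18435. Lcn2, another injury marker, had 473 and 2 counts, a ratio of 235, 95% interval 64.7 to 1945. Spp1 rose by 3.85 ± 0.24 and Sox9, a gene of tubular repair, by 3.41 ± 0.52. The phosphate transporter Slc34a1 fell by 2.51 ± 0.27 on the log2 scale and the endocytic receptor Lrp2 by 1.74 ± 0.11. The organic anion transporter Slc22a6 fell by 1.60 ± 0.13, the amino acid transporter Slc7a13 by 5.37 ± 0.25 and the methyltransferase Inmt by 5.73 ± 0.20. Pde6a was at 0 in both cisplatin libraries and at least 8.73-fold lower, counting 3 as the floor over the group. Serpina10 and Saa1, at 0 in both CMCTween libraries, were at least 21.5-fold and 20.9-fold higher. Against the 3 control groups the log2 fold change was 8.15 for Havcr1, 7.89 for Cdkn1a and -3.08 for Slc34a1.

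In all, 1152 genes rose and 1189 fell in the cisplatin kidney within the set, of 10164 tested, against 2476 and 2476 with the 3 control groups, and 1650 genes passed both with the same sign. Without cisplatin replicate 1 the count within the set was 1337, and Pcna, a replication gene at 1.09 ± 0.33, lost its call (adjusted p = 0.137, and 0.0818 without CMCTween replicate 4). Of 21 p53 targets, 19 rose and none fell (19 adjusted over the list alone, median 2.28, fry adjusted p = 4.57e-13). All 14 kidney injury genes rose (14 adjusted over the list alone, median 3.33, adjusted p = 1.75e-11). Of 15 proximal tubule transport genes, 14 fell (14 down and 1 up adjusted over the list alone, median -1.44, adjusted p = 4.80e-10), and the sulfate transporter Slc13a1 did not pass, at 0.71 ± 0.30 (adjusted p = 0.102), but passed against the other groups of the set, at 0.74 (adjusted p = 0.0108). Of 15 NRF2 targets, genes of the oxidant response, 8 rose, among them Gclc at 1.32 ± 0.21 and Nqo1 at 1.04 ± 0.21. Me1 of the same list fell by 1.39 ± 0.13 (10 up and 2 down adjusted over the list alone, median 0.97, adjusted p = 1.78e-10). These 4 lists also passed with an estimated correlation, and with the 3 control groups. Of 11 cell cycle genes 1 rose (1 adjusted over the list alone, median 0.24, adjusted p = 0.544), where the planned comparison gave 3 up and 1 down with an adjusted p of 0.0215 (adjusted p = 0.820 with an estimated correlation).

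In bone marrow cisplatin removed the transcripts of red cell precursors. Slc4a1 (band 3, chromosome 11, 102348824 to 102366203), the anion exchanger of the red cell membrane, had 2 counts against 2969 in CMCTween, a ratio of 0.000841, 95% interval 0.000102 to 0.00304. The heme synthesis gene Alas2 fell by 8.89 ± 0.56 (SE, n = 2 against 2, adjusted p = 2.47e-10). The erythroid gene Trim10 was at 0 in both cisplatin libraries, at least 195-fold lower. The proliferation marker Mki67 fell by 1.60 ± 0.13, Top2a by 0.71 ± 0.11 and Cdk1 by 0.71 ± 0.16. Among B cell genes Vpreb3 fell by 4.45 ± 0.55 and Ms4a1 (CD20) by 1.36 ± 0.21. Of genes that rose, Vcan rose by 4.04 ± 0.40, Ms4a8a by 3.69 ± 0.40, Fn1 by 2.74 ± 0.13, Chil3 by 2.56 ± 0.12 and the neutrophil elastase gene Elane by 0.96 ± 0.19. Of the p53 targets, Cdkn1a rose by 1.44 ± 0.27 and Btg2 fell by 1.56 ± 0.17.

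The bone marrow counts for cisplatin were 720 up and 1017 down of 9194 genes within the set and 1742 and 2082 with the 3 control groups, with 1288 in both. Without CMCTween replicate 4 the count was 1042. All 8 erythroid genes fell (8 adjusted over the list alone, median -9.32, or -8.41 with genes at 0 put at their bound, adjusted p = 3.18e-12). Of 10 B cell genes 9 fell (10 adjusted over the list alone, median -1.55, adjusted p = 2.41e-06) and of 12 neutrophil genes 7 rose (9 adjusted over the list alone, median 0.54, adjusted p = 4.84e-06). In the planned comparison 6 neutrophil genes rose and 2 fell (adjusted p = 1.27e-05), and that call and the B cell call were lost there with an estimated correlation (adjusted p = 0.291 and 0.183). Of 25 cell cycle genes 15 fell (15 adjusted over the list alone, median -0.57, adjusted p = 5.95e-06, but adjusted p = 0.0808 with an estimated correlation). Of 13 p53 targets 2 rose and 1 fell (2 and 1 adjusted over the list alone, median 0.20, adjusted p = 0.724), and in the planned comparison their median was -0.42 while the test pointed up (adjusted p = 0.682). The response differed between kidney and bone marrow for 1290 of 11113 genes in a joint fit of both tissues.

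APAP, read from its label as 2 hours after acetaminophen, a liver toxicant through its reactive metabolite, raised immediate early and stress genes in liver. The transcription factor genes Egr1 (chromosome 18, 34859823 to 34864984) and Jun rose by 6.05 ± 0.57 and 5.84 ± 0.31 (SE, n = 2 against 4, adjusted p = 3.37e-07 and 5.00e-11). Atf3, a stress-induced factor, rose by 8.06 ± 0.68, Cdkn1a by 5.57 ± 0.54, the heme oxygenase gene Hmox1 by 4.73 ± 0.22 and the metallothionein genes Mt1 and Mt2 by 4.65 ± 0.71 and 5.33 ± 0.71. Fos had 128 counts against 3 (ratio 375, 95% interval 126 to 1844) and the hormone gene Fgf21 72 against 2 (ratio 317, 95% interval 84.6 to 2665). Of genes that fell, the lipid synthesis regulators Srebf1 and Mid1ip1 fell by 3.32 ± 0.51 and 3.43 ± 0.50, Car3 by 3.42 ± 0.41 and the peroxisomal gene Nudt7 by 3.18 ± 0.34. Hsd3b5, a steroid metabolism gene of male liver, had 1 count against 2372 (ratio 0.00371, 95% interval 9.39e-05 to 0.0207). Against the 3 control groups Egr1 was at 7.18, Jun at 5.68 and Hmox1 at 5.16.

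Within its set 638 genes rose and 721 fell of 8242 in the APAP liver, against 844 and 770 planned, with 941 in both. The count was 627 without APAP replicate 1 and 838 without replicate 2. All 12 immediate early genes rose (12 adjusted over the list alone, median 3.74, adjusted p = 4.75e-09). Of 11 genes of the integrated stress response 7 rose, among them Ddit3 at 2.58 ± 0.41 and Atf4 at 1.26 ± 0.14 (8 up and 1 down adjusted over the list alone, median 1.77, adjusted p = 4.57e-13). Of 13 NRF2 targets 6 rose, Srxn1 by 1.25 ± 0.17, and 3 fell, among them Gstm1 by 0.72 ± 0.20 (6 and 3 adjusted over the list alone, median 0.27, adjusted p = 4.02e-06). Gstm1 lost its call without APAP replicate 1 (adjusted p = 0.120) or 2 (0.128). Of 11 glucocorticoid-responsive genes 6 rose, Fkbp5 by 2.04 ± 0.39 (7 adjusted over the list alone, median 1.31, adjusted p = 6.69e-05). These 4 lists passed with an estimated correlation within the set, but in the planned comparison the NRF2 and glucocorticoid lists did not (adjusted p = 0.0662 and 0.155). Of 14 genes of xenobiotic metabolism 4 rose, Cyp2b10 by 3.15 ± 0.47, and 3 fell, Cyp2c29 by 1.29 ± 0.24 (6 and 3 adjusted over the list alone, median 0.44, adjusted p = 0.214), and the planned median was -0.06. Of 16 acute phase genes only Hp passed, at 0.96 ± 0.27 (1 adjusted over the list alone, median -0.13, adjusted p = 0.898, with a planned test that pointed up at a median of -0.02). Its call was lost without Untreated replicate 2 (adjusted p = 0.0554), Sucrose replicate 1 (0.0684), APAP replicate 1 (0.0866) or 2 (0.133).

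Teriparatide, a parathyroid hormone fragment that acts on bone, raised matrix and osteoclast genes in skull, beside genes not known for bone. Wif1 (chromosome 10, 121033960 to 121100650), a secreted Wnt inhibitor made by osteoblasts, rose by 2.22 ± 0.22 (SE, n = 2 against 2, adjusted p = 2.72e-09). The osteocyte gene Phex rose by 1.54 ± 0.23, the sphingomyelinase gene Smpd3 by 1.79 ± 0.25, the bone sialoprotein gene Ibsp by 0.95 ± 0.15 and the osteoclast protease gene Mmp9 by 1.15 ± 0.14. Each of these 5 kept its call when any 1 of the 4 libraries was left out. The collagen gene Col1a2 rose by 1.41 ± 0.28 (adjusted p = 0.00930), a call lost without CMCTween replicate 4 (adjusted p = 0.220), teriparatide replicate 1 (0.0517) or 2 (0.0853), and the osteoclast phosphatase gene Acp5 by 1.35 ± 0.23 (adjusted p = 0.00169), a call lost without CMCTween replicate 4 (adjusted p = 0.0950). Of the genes with the largest rise, the odorant-binding gene Obp1a, at 0 in both CMCTween libraries, was at least 15.3-fold higher (50 counts), a call lost without CMCTween replicate 3 (adjusted p = 0.174), 4 (0.315), teriparatide replicate 1 (0.138) or 2 (0.144), and the aldehyde dehydrogenase gene Aldh3a1 of epithelia rose by 3.30 ± 0.48. Sost, for sclerostin, did not pass, at -0.97 ± 0.31 (adjusted p = 0.0941), but passed against the other groups of the set, at -1.03 (adjusted p = 0.00971). Within the set 163 genes rose and 61 fell of 10598, against 1633 and 1705 planned, with 168 in both. The count was 121 without CMCTween replicate 3, 35 without CMCTween replicate 4, 84 without teriparatide replicate 1 and 57 without replicate 2. Of 17 osteoblast and osteocyte genes 10 rose (12 up and 1 down adjusted over the list alone, median 1.32, adjusted p = 0.000257). Of 14 osteoclast genes 5 rose and Car2 fell by 0.64 ± 0.15 (11 and 1 adjusted over the list alone, median 0.95, adjusted p = 6.80e-05), although Car2, which red cell precursors also express, had the opposite sign against the other groups of the set (0.22, adjusted p = 0.343), and its call was lost without CMCTween replicate 4 (adjusted p = 0.191), teriparatide replicate 1 (0.0625) or 2 (0.180). Both lists passed with an estimated correlation and in the planned comparison. Of 6 genes of the cAMP response 1 rose (1 adjusted over the list alone, median 0.69, adjusted p = 0.0134, but adjusted p = 0.0834 with an estimated correlation).

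Sofosbuvir, an antiviral nucleotide, raised 2 serum amyloid genes in liver. Saa2 (chromosome 7, 46751790 to 46754313) rose by 5.91 ± 0.77 (SE, n = 2 against 4, adjusted p = 0.000306), Saa1 by 4.62 ± 0.70, the chemokine gene Cxcl1 by 5.14 ± 0.72, Mt2 by 4.82 ± 0.70 and the calcium-binding gene Pvalb by 4.59 ± 0.71. Against the 3 control groups Saa2 was at 6.18 and Cxcl1 at 7.15. Cyp2e1, a cytochrome gene, fell by 0.94 ± 0.21 (adjusted p = 0.0254), and lost its call without Untreated replicate 2 (adjusted p = 0.0638), 4 (0.0603), Sucrose replicate 2 (0.0830), sofosbuvir replicate 1 (0.247) or 2 (0.290). Within the set 82 genes rose and 22 fell, against 320 and 200 planned, with 66 in both. The count was 67 without Untreated replicate 2, 64 without Sucrose replicate 2, 28 without sofosbuvir replicate 1 and 19 without replicate 2. Of 23 cholesterol synthesis genes 2 fell, among them Tmem97 (-0.96 ± 0.21) (14 down adjusted over the list alone, median -0.76, adjusted p = 0.0316, but adjusted p = 0.122 with an estimated correlation and 0.265 planned). The call of Tmem97 was lost without sofosbuvir replicate 1 (adjusted p = 0.0872) or 2 (0.286). Of 14 xenobiotic metabolism genes Cyp3a13 rose by 0.74 ± 0.16, a call lost without Untreated replicate 2 (adjusted p = 0.0571), Sucrose replicate 1 (0.0569), 2 (0.0591), sofosbuvir replicate 1 (0.0943) or 2 (0.282) (2 adjusted over the list alone, median 0.09, adjusted p = 0.215, planned median -0.13). Of 9 interferon genes none passed by edgeR, alone or over all genes (median 0.21 with a test that pointed down, adjusted p = 0.976).

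The other set C comparisons gave 1 to 16 genes within the set, where the planned reference gave 1142 to 2251 in each direction. Against all other groups of the set Dox gave 205 up and 45 down in bone marrow and 37 and 9 in heart. EMPA gave 24 and 6 in kidney and 17 and 6 in liver, lenalidomide 70 and 2 and Repatha 12 and 8. In brain aripiprazole gave 6 and 3 there and clozapine 1 and 1. Genes in this and the next 2 paragraphs that the naming rule leaves out were chosen after their values were seen. In heart, Dox (lists chosen for doxorubicin, a cardiotoxic drug, although the label does not spell the name out and doxycycline shares it) raised 10 genes and lowered 6. Of the genes the naming rule allows, Tacc2, a cytoskeletal gene, fell by 0.68 ± 0.14 (adjusted p = 0.00775), lost without CMCTween replicate 4 (adjusted p = 0.388), Dox replicate 3 (0.0680) or 4 (0.285), and the sarcomere gene Actc1 (0.20 ± 0.10) and the stress hormone gene Nppa (0.19 ± 0.12) did not pass. Against the other groups of the set Actc1 passed, at 0.46 (adjusted p = 0.000354), and planned it was at 1.12 (adjusted p = 1.96e-15). Leaving out any 1 of the 4 libraries gave 4 to 7 genes. In bone marrow Dox raised Snrpd1 (0.80 ± 0.16) and the proteasome gene Psme3 (0.74 ± 0.16) and lowered the receptor genes Lilr4b (-1.32 ± 0.28) and Fpr2 (-0.67 ± 0.13), and every one of these calls was lost whichever of the 4 libraries was left out (adjusted p from 0.0622 to 0.509, 841 genes at an unadjusted p under 0.05, 11 by DESeq2). Planned, Snrpd1 and Fpr2 passed with the opposite sign, at -0.59 and 0.41 (adjusted p = 6.18e-05 and 0.00279), Psme3 was at 0.76 and Lilr4b at -0.42 (adjusted p = 0.204). EMPA, read as the kidney glucose transport inhibitor empagliflozin, lowered 5 genes in kidney: Uap1 (-1.11 ± 0.20), Lrrc58 (-0.70 ± 0.12), Slain2 (-0.82 ± 0.18), Prnp (-0.62 ± 0.13) and 2900060B14Rik (-0.98 ± 0.18). Planned, 2900060B14Rik, Lrrc58 and Slain2 passed with the opposite sign, at 2.25, 0.62 and 0.36 (adjusted p = 2.96e-11, 4.17e-07 and 0.0476), and Prnp was at 0.17 (0.216). All 5 calls were lost without CMCTween replicate 4 (adjusted p from 0.338 to 0.586) or EMPA replicate 1 (0.156 to 0.623), that of 2900060B14Rik without CMCTween replicate 3 (0.121) or EMPA replicate 2 (0.320), of Slain2 without CMCTween replicate 3 (0.0834) or EMPA replicate 2 (0.135) and of Prnp without CMCTween replicate 3 (0.0825). The counts were 0, 2 and 3 genes without CMCTween replicate 4, EMPA replicate 1 and CMCTween replicate 3, the 2 being genes outside these 5 (715 genes at an unadjusted p under 0.05, 4 by DESeq2). Its bicarbonate transporter Slc4a4 did not pass, at 0.29 ± 0.10, but passed against the other groups of the set, at 0.40 (adjusted p = 0.00292), and planned, at 1.51 (adjusted p = 5.62e-28). Its target Slc5a2 did not pass the low-count filter, with at most 4 counts in any of 36 kidney libraries. In liver EMPA raised the noncoding RNA Malat1 (0.72 ± 0.10), a call lost without CMCTween replicate 3 (adjusted p = 0.0522), and 3 genes passed without CMCTween replicate 4 (629 genes at an unadjusted p under 0.05, 1 by DESeq2). Lenalidomide, a drug that degrades Ikaros in human cells, raised Gapdh (0.81 ± 0.14), Psme3 (0.79 ± 0.16) and Ly6e (0.72 ± 0.15) in bone marrow. Psme3 and Ly6e lost their calls without CMCTween replicate 3, CMCTween replicate 4 or lenalidomide replicate 4. Gapdh lost its call without CMCTween replicate 4 or lenalidomide replicate 4. Repatha, a cholesterol-lowering antibody, raised Malat1 (0.62 ± 0.10) and the transcription factor gene Zbtb20 (1.17 ± 0.23) in liver, with 0 genes without CMCTween replicate 3 or Repatha replicate 1 and 1 without CMCTween replicate 4 (707 genes at an unadjusted p under 0.05, 13 by DESeq2). Malat1 lost its call without CMCTween replicate 3 (adjusted p = 0.10) or Repatha replicate 1 (0.172), and Zbtb20 without CMCTween replicate 3 (adjusted p = 0.10), 4 (0.252), Repatha replicate 1 (0.123) or 3 (0.145). Against the other groups of the set, Gapdh, Ly6e, both Repatha genes, Snrpd1, Lilr4b, Lrrc58, Prnp and 2900060B14Rik also lost their calls (adjusted p from 0.0693 to 0.320).

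No planned list passed for these 4 drugs within the set. For Dox in heart the medians were -0.08 for p53 targets (adjusted p = 0.544), 0.07 for cell cycle (0.976), -0.18 for stress and fibrosis genes (test up, 0.976) and 0.02 for contractile genes (test down, 0.866), with no gene past adjusted p 0.05 over the list alone. In bone marrow Dox gave 0.07 for p53 targets (0.597), 0.28 for cell cycle (2 up adjusted over the list alone, 0.103), -0.23 for neutrophil genes (5 down, 0.148), 0.30 for erythroid genes (0.384) and 0.35 for B cell genes (1 up, 0.217). EMPA in kidney gave -0.09 for tubule transport (1 up and 1 down adjusted over the list alone, 0.724), 0.13 for fatty acid oxidation (1 down, 0.866) and -0.17 for gluconeogenesis (test up, 1 up, 0.991). In liver it gave 0.46 for lipogenesis (5 up, 0.0568), -0.15 for fatty acid oxidation (2 down, 0.214) and 0.01 for gluconeogenesis (0.724). Lenalidomide gave 0.07 for cell cycle (1 down, 0.898), 0.43 for interferon (0.260), 0.11 for neutrophil (1 up, 0.544), 0.11 for erythroid (1 down, 0.976), 0.09 for B cell (0.652) and -0.11 for Ikaros axis genes (0.959). Repatha gave 0.81 for cholesterol synthesis (2 up, 0.0568) and 0.26 for lipogenesis (1 up, 0.328). With the 3 control groups 5 of these lists passed. They were p53 targets in the Dox heart (down, 0.00514), cell cycle (up, 0.0267), neutrophil (down, 0.000187) and B cell genes (up, 0.0478) in the Dox bone marrow and Ikaros axis genes for lenalidomide (up, 0.0396). None of them passed with an estimated correlation (adjusted p = 0.529, 0.694, 0.291, 0.696 and 0.661).

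Alendronate and risedronate are bisphosphonates, which inhibit osteoclasts, and a direct comparison in skull asked whether they differ. No gene of 10598 did (edgeR, 688 at an unadjusted p under 0.05, 0 by DESeq2), although 70 passed without alendronate replicate 2. The median SE of a difference was 0.35, and the interval for the osteoclast gene Acp5 was -0.74 to 0.18, that for Ctsk -0.69 to 0.46 and for the osteoblast gene Bglap -1.65 to -0.23 (adjusted p = 0.682). Against the other 4 drugs of set B, 9 genes rose and 4 fell with alendronate, 1 rose with risedronate, and planned the counts were 1172 up and 1198 down, and 1151 and 1157. The fucosyltransferase gene Fut8 rose by 0.90 ± 0.17 and the RNA Malat1 by 0.59 ± 0.11. The 4 that fell were Klf13 (-1.05 ± 0.16), Hnrnpl (-0.87 ± 0.19), S100a11 (-0.79 ± 0.16) and Hp (-0.69 ± 0.15). Hnrnpl was also lower outside set A, by a median log2 of -2.29 over 23 tissues, and whether its fall here is part of that shift was not tested. Planned, S100a11 passed with the opposite sign, at 0.66 (adjusted p = 0.00250). All 13 calls were lost without alendronate replicate 1 (adjusted p = 0.505 for Fut8, 0.508 for Malat1 and 0.178 for Klf13). Those of Hnrnpl, S100a11 and Hp were also lost without asenapine replicate 3 (0.0635), lurasidone replicate 2 (0.0718), olanzapine replicate 2 (0.0780) or risedronate replicate 1 (0.0954), without asenapine replicate 3 (0.0605), lurasidone replicate 2 (0.0664), olanzapine replicate 1 (0.0629) or risedronate replicate 1 (0.0703) and without asenapine replicate 4 (0.124), lurasidone replicate 2 (0.0999), olanzapine replicate 1 (0.101) or risedronate replicate 1 (0.0954). Without alendronate replicate 2, 72 genes passed, 6 without lurasidone replicate 2 and 7 without risedronate replicate 1. With risedronate the chaperone gene Dnaja1 rose by 0.88 ± 0.16 (833 genes at an unadjusted p under 0.05, 0 by DESeq2). That call was lost without asenapine replicate 3 (adjusted p = 0.0827), lurasidone replicate 1 (0.0572), olanzapine replicate 1 (0.0550) or risedronate replicate 1 (0.797), and 19 genes passed without alendronate replicate 2 and 4 without lurasidone replicate 2. Acp5 was at -0.37 ± 0.19 with alendronate and Ctsk at 0.20 ± 0.23 with risedronate, neither passing. Each bisphosphonate is part of the other's reference, so an effect they share is partly subtracted in these values and in the list tests. No list passed: cholesterol synthesis was at a median of 0.08 with alendronate (3 up adjusted over the list alone, adjusted p = 0.0675) and 0.15 with risedronate (0.652), osteoclast genes at 0.10 (0.976) and -0.03 (0.963), and osteoblast genes at -0.20 (1 down, 0.724) and -0.01 (test up, 0.909). The planned osteoblast test passed for risedronate (up at a median of -0.01, 0.0424, but adjusted p = 0.623 with an estimated correlation), and the planned osteoclast test pointed up at -0.13 (0.424).

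The 5 antipsychotics were compared in brain. Asenapine, lurasidone and olanzapine are part of each other's references, so an effect these drugs share is partly subtracted. Their values are therefore not like those of aripiprazole and clozapine against CMCTween. Against the other 4 drugs of its set, asenapine (4 libraries against 8) raised Txnip (chromosome 3, 96557957 to 96561883), a glucose-responsive inhibitor of thioredoxin, by 1.47 ± 0.20 (SE, adjusted p = 2.98e-07) and Ppp1r1b, the striatal dopamine effector DARPP-32, by 0.39 ± 0.09 (adjusted p = 0.000582), and lowered the immediate early gene Arc by 1.07 ± 0.25 (adjusted p = 0.00377). Planned, Txnip was at 0.89 (adjusted p = 5.38e-05) and Arc at -0.73 (0.0228). Ppp1r1b did not pass planned, at 0.18 (adjusted p = 0.0820), and was at -0.0338 against Untreated alone (0.807). Within the set 707 genes rose and 858 fell of 10095, against 1798 and 2156 planned, with 740 in both and 869 without asenapine replicate 2. Of 12 immediate early genes Arc and Jun (-0.40 ± 0.13, planned -0.07 with adjusted p = 0.724) fell (2 adjusted over the list alone, median -0.14, adjusted p = 0.160). Of 11 striatal genes Ppp1r1b and Penk (0.33 ± 0.09, planned 0.35 with adjusted p = 0.00134) rose and 1 fell (2 and 1 adjusted over the list alone, median 0.10, adjusted p = 0.337). Jun and Penk lost their calls without asenapine replicate 1 (adjusted p = 0.131 and 0.120) or 2 (0.152 and 0.0599), Jun also without alendronate replicate 2 (0.0800), olanzapine replicate 2 (0.0663) or risedronate replicate 1 (0.103). Of 22 cholesterol genes 1 rose and 1 fell (1 and 1 adjusted over the list alone, median -0.01 with a test that pointed up, adjusted p = 0.940).

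Olanzapine (2 libraries against 10) raised 582 genes and lowered 411 in brain, 1638 and 1610 planned, with 733 in both. Lrrc47 (chromosome 4, 154011731 to 154021513), a leucine-rich repeat gene, rose by 1.89 ± 0.29, Mgat5, a glycosyltransferase gene, by 2.60 ± 0.52 and Dnajb12, a chaperone gene, by 2.02 ± 0.37 (adjusted p = 1.34e-06, 0.000196 and 3.04e-05). The count was 265 without olanzapine replicate 1 and 346 without replicate 2. The phosphodiesterase gene Pde10a rose by 0.64 ± 0.19, lost without replicate 1 (adjusted p = 0.153) or 2 (0.202), and the sterol gene Fdps fell by 1.16 ± 0.37, lost without replicate 1 (0.120) or 2 (0.322). Lurasidone raised 362 and lowered 268, 1119 and 1179 planned, with 208 in both, and the count was 92 without lurasidone replicate 1 and 336 without replicate 2. Grip2, a glutamate receptor scaffold gene, rose by 1.57 ± 0.37 (adjusted p = 0.00299) and Acvr2a, an activin receptor gene, fell by 1.99 ± 0.49 (0.00502), calls lost without lurasidone replicate 1 (adjusted p = 0.0848 and 0.237) and for Grip2 also without replicate 2 (0.0571). Aripiprazole (2 against 2) raised 11 genes and lowered 3, 1610 and 1772 planned. The glycolysis gene Gapdh rose by 1.18 ± 0.11 (adjusted p = 5.54e-15) and the synaptic gene Nrgn by 0.57 ± 0.09 (adjusted p = 0.0554 without CMCTween replicate 4). Pisd-ps1 (-1.34 ± 0.18), Ranbp1 (-1.32 ± 0.27) and Malat1 (-0.43 ± 0.09) fell. Ranbp1 lost its call without CMCTween replicate 3 (adjusted p = 0.179), 4 (0.0554), aripiprazole replicate 2 (0.0910) or 4 (0.269) and Malat1 without CMCTween replicate 4 (adjusted p = 0.454), aripiprazole replicate 2 (0.178) or 4 (0.199). The count was 6 without CMCTween replicate 3, 3 without CMCTween replicate 4, 3 without aripiprazole replicate 2 and 7 without replicate 4. Clozapine raised 10 genes, among them Gapdh (0.75 ± 0.11), and lowered Pisd-ps1 (-1.51 ± 0.18), 1854 and 1968 planned, with 3, 4 and 4 genes without CMCTween replicate 3, CMCTween replicate 4 and clozapine replicate 4. Against the other groups of the set Gapdh had an adjusted p of 0.937 with clozapine and 2.21e-07 with aripiprazole.

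Immediate early genes had a median of -0.61 with clozapine (no gene passing, 3 down adjusted over the list alone, adjusted p = 0.0273, also past 0.05 with an estimated correlation), -0.65 with aripiprazole (4 down, 0.0568), -0.21 with lurasidone (0.328) and -0.03 with olanzapine (test up, 0.960). Fos was at -2.58 ± 0.60 with aripiprazole and -1.07 ± 0.46 with clozapine, and Arc at -1.33 ± 0.43 and -1.50 ± 0.41, none passing within the set. In the planned comparison this list was lower with clozapine (0.000402), aripiprazole (0.00113) and asenapine (0.0214), but with an estimated correlation the adjusted p values were 0.426, 0.454 and 0.785. Cholesterol genes were at -0.12 with aripiprazole (1 down adjusted over the list alone, 0.328), -0.03 with clozapine (1 down, test up, 0.976), -0.08 with lurasidone (Idi1 down at -1.92 ± 0.58, lost without either lurasidone library at 0.398 and 0.168, none over the list alone, 0.652) and -0.04 with olanzapine (1 up and 2 down, 0.685). All 5 drugs lowered them in the planned comparison (adjusted p from 4.87e-05 to 0.00203), none with an estimated correlation (0.291 to 0.601). Striatal genes were at 0.02 with aripiprazole (test down, 0.960), 0.00 with clozapine (1 up, 0.866), 0.13 with lurasidone (0.203) and 0.01 with olanzapine (2 up, 0.652). Planned, they passed for clozapine (test up at a median of -0.08, 0.0424, but adjusted p = 0.796 with an estimated correlation), and median and test also had opposite signs for asenapine (-0.08).

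Clozapine and olanzapine, which share a tricyclic core, differed by 170 genes up and 384 down in brain (1810 at an unadjusted p under 0.05), but the pair lies in different sets, so drug and set cannot be told apart. Arc was lower with clozapine by 1.79 (interval -2.64 to -0.93, adjusted p = 0.0128) and Jun by 0.67 (-1.07 to -0.26, adjusted p = 0.0348). Leaving out clozapine replicate 3 or 4 or olanzapine replicate 1 or 2 gave 288, 241, 191 and 277 genes. The pancreas enzyme genes Cpa1 and Rnase1 were higher with olanzapine, at 29.5 and 29.7 CPM against 0.30 and 0.63. As a class against the 3 control groups the 5 drugs changed 2881 genes in brain, 2681 in pituitary and 1954 in liver, and aripiprazole and clozapine against CMCTween changed 25, 23 and 26, of which 14, 9 and 9 were also in the class count. The 4 largest rises of the class in brain were pancreas enzyme genes, Cpa1 (4.58), Ctrb1 (4.47), Rnase1 (4.21) and Cpb1 (3.33), none passing within set C (adjusted p from 0.781 to 0.994). Not all 5 drugs shared them, since Cpa1 and Rnase1 with clozapine, at 0.30 and 0.63 CPM, lay near the controls, at 0.56 and 0.66. Carry-over of pancreas RNA or reads was not tested, so these values cannot be read as an effect of the class. Hnrnpl, at -2.18 in the class in brain and -2.01 in pituitary, was at -0.29 and 0.08 within set C, and in liver the class genes Cdkn1a (3.44) and Mt1 (2.86) were at 1.87 and 2.07, with adjusted p of 0.394 and 0.434.

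The labels do not say whether tissues of a drug come from the same mice, so counts of tissues may not be independent results. Across tissues, the p53 target list was raised by cisplatin in 21 of 24 tissues within the set and in 21 planned (14 and 7 with an estimated correlation). APAP raised it in 17 (23 planned, 3 and 9 with an estimated correlation), and Dox raised it in 1 and lowered it in 1 (10 lowered planned, none with an estimated correlation). Cdkn1a rose in 23 of 24 tissues with APAP (median 2.40) and in 19 with cisplatin (median 1.75), and Mdm2 in 10 with cisplatin (median 0.62), where the planned comparison gave 6 up and 10 down. With APAP Mdm2 rose in 1 tissue and fell in 2 (median -0.04), against 11 up planned. In the planned comparison Cdkn1a also passed in 24 tissues for aripiprazole and 23 for olanzapine, and in no tissue within sets. For asenapine it rose in 22 tissues planned and in 7 within the set. For alendronate it rose in 6 planned and fell in 3 within the set. Of the clock genes, Arntl rose in 10 of 20 tissues with APAP, Per2 fell in 4 of 23 with APAP and Nr1d1 rose in 7 of 23 with asenapine, while Dbp did not pass the filter in any tissue (at most 7 counts in a library). In pituitary no drug changed the prolactin gene Prl within its set, and cisplatin raised the growth hormone gene Gh by 1.04 ± 0.21 (adjusted p = 0.0113). Against the other groups of the set Gh was at 0.61 with cisplatin (adjusted p = 0.0215). The other set C drugs also lay above CMCTween for Gh, from 0.15 with lenalidomide to 0.98 with aripiprazole, none passing. Part of the cisplatin value may therefore come from a low CMCTween group.

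**Figure D3:**
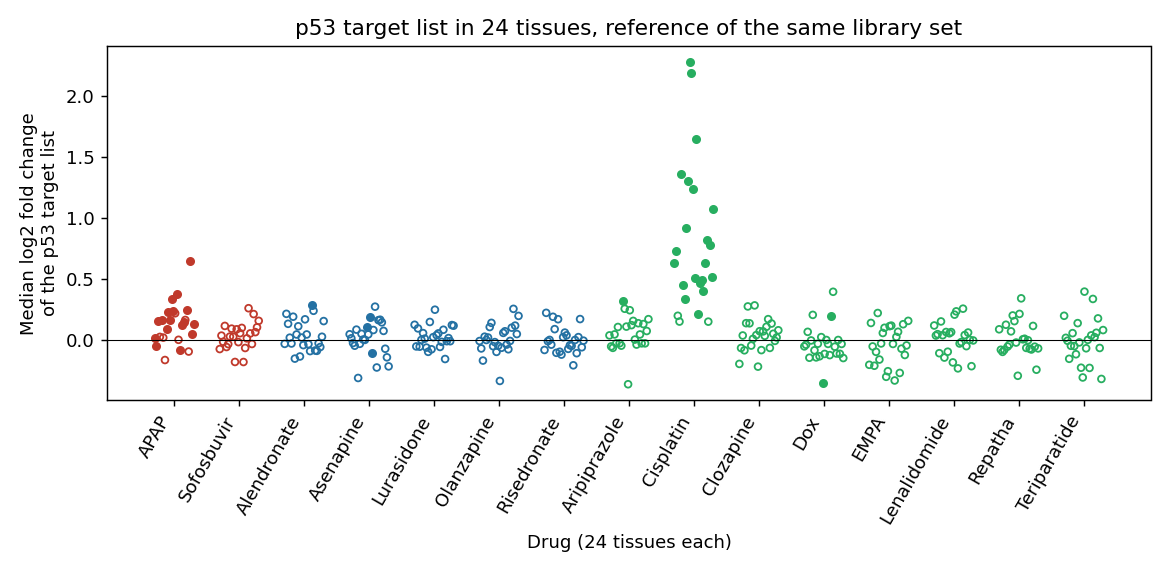
Median log2 fold change of the p53 target list in 24 tissues (points) for each of 15 drugs (horizontal axis), reference of the same set. Filled points have an adjusted p under 0.05, 21 for cisplatin and 17 for APAP, and colour gives the library set.

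Over the 360 pairs the set references gave 102826 calls, the planned reference 926387. Cisplatin had 27302, APAP 24576, asenapine 11923, olanzapine 8422 and lenalidomide 282. Against all other groups of the set, cisplatin had 42908, APAP 23557 and lenalidomide 2092, while for asenapine and olanzapine this is the same reference. The 10 pairs with most calls within sets were cisplatin in thymus (4748), ileum (3243), skeletal muscle (3146), kidney (2341) and bone marrow (1737). The others were APAP in thymus (2783), skeletal muscle (2424), jejunum (2348), ileum (1798) and white fat (1717). In the cisplatin thymus the recombinase gene Rag2 had 1 count against 285 (ratio 0.00341, 95% interval 8.61e-05 to 0.0192), and the muscle ubiquitin ligase gene Trim63 was at least 22.4-fold higher. In the cisplatin ileum Saa3 rose by 8.06 ± 0.44 and the stem cell gene Olfm4 was at least 39.5-fold lower. In skeletal muscle cisplatin left the muscle gene Tmem233 at least 70.8-fold lower, and APAP raised the acyl-CoA thioesterase gene Acot1 by 6.50 ± 0.59 and the fuel switch gene Pdk4 by 4.89 ± 0.52 and lowered Ky by 4.23 ± 0.18. APAP raised Cyp3a11 by 4.90 ± 0.90 in ileum. It raised Cyp4a10, of fatty acid oxidation, by 5.50 ± 0.99 in jejunum, and it left the mitosis genes Nek2 and Cdkn3 at least 5.53-fold and 3.75-fold lower in thymus. Over all 12585 list tests in the 360 pairs 838 passed within sets and 3290 planned (130 and 58 with an estimated correlation).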

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

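The list tests between tissues below were planned, with the reference within the library set chosen after the data were seen. In 4 lists the response to cisplatin differed between kidney and bone marrow, tested as the difference itself in a joint fit of the 36 libraries of set C in both tissues with 2 libraries per group, and with the median log2 difference over the list as its size. The difference, kidney minus bone marrow, was 1.66 for the p53 target list (fry adjusted p = 1.90e-08), 3.20 for the kidney injury list (adjusted p = 7.87e-06), 0.78 for the NRF2 target list (adjusted p = 5.93e-07) and 0.91 for the cell cycle list (adjusted p = 0.0416). The cell cycle list fell in bone marrow (adjusted p = 5.95e-06, but 0.0808 with an estimated correlation) and did not pass in kidney, so its difference is no rise in kidney. The joint fit keeps genes that pass the filter through either tissue (25 cell cycle genes, of which 11 passed in the kidney fit). The differences therefore also hold genes that 1 of the tissues barely expresses, and for these they do not compare responses. With an estimated correlation the first 3 differences also passed (adjusted p = 0.000421, 0.0162 and 0.0162), and that of the cell cycle list did not (adjusted p = 0.583). Of the other lists tested between these tissues, the erythroid list had a median difference of 6.91 (adjusted p = 0.115). The tissues hold different cell types, and no biological or technical explanation of these differences was tested. The joint fit takes all libraries as independent, although those of both tissues may come from the same mice. In 16 sets of values from 4 libraries no value lay apart from the rest by Dixon's test.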

How the results depend on the processing

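The comparisons within library sets, the set references, the other groups of a set and the fit of the set alone are tests chosen after seeing the data, and the other alternatives were planned. With RLE size factors all 48 counts stayed within 1.5 times. With the replicate block 41 of 48 counts did so, without the filter 36 of 48, with DESeq2 29 of 46, and when 1 library was left out 185 of 266. For the results below that moved, the cause was not tested, except that a left-out library lowers the number of libraries. A 2-library group without 1 library is left with 1, assumed to vary like the other groups. The replicate numbers of the labels did not pair samples of different treatments (median correlation of replicate differences between treatments 0.0103 over 1113 pairs), so the block is a check and no pairing. Whether the same number in different tissues is the same mouse is not stated in the labels and was not tested. Slc5a2 in kidney and Dbp in every tissue were below the filter, with at most 4 and 7 counts in any library, the deeper Untreated libraries included, and the cause was not tested.

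Changing the reference moved the planned counts most. The reference of the same library set gave 2341 (cisplatin in kidney), 1737 (cisplatin in bone marrow), 16 (Dox in heart), 4 (Dox in bone marrow), 5 (EMPA in kidney) and 1 (EMPA in liver). It gave 13 (alendronate), 1 (risedronate), 224 (teriparatide), 3 (lenalidomide), 2 (Repatha), 104 (sofosbuvir), 14 (aripiprazole), 1565 (asenapine), 11 (clozapine), 630 (lurasidone) and 993 (olanzapine). Untreated alone gave 4284 (Dox in heart), 4898 (Dox in bone marrow), 4344 (EMPA in liver), 4107 (alendronate), 4134 (risedronate), 4325 (lenalidomide), 3909 (Repatha), 1030 (sofosbuvir) and 3721 (lurasidone). For sofosbuvir, Untreated is also part of the set reference, so its count of 104 depends on averaging Untreated with Sucrose. The vehicles alone gave 1188 (Dox in heart), 1342 (Dox in bone marrow), 2376 (EMPA in kidney), 1061 (EMPA in liver), 1028 (alendronate), 1089 (risedronate), 1935 (teriparatide), 1031 (lenalidomide), 1079 (Repatha), 1167 (sofosbuvir), 1867 (aripiprazole), 2242 (clozapine) and 2030 (olanzapine). The mean of the other 17 groups gave 234 (Dox in heart), 869 (Dox in bone marrow), 3411 (APAP), 1654 (EMPA in kidney), 717 (EMPA in liver), 639 (alendronate), 686 (risedronate), 1197 (teriparatide), 489 (lenalidomide), 727 (Repatha), 3004 (sofosbuvir), 882 (aripiprazole), 1234 (clozapine), 1254 (lurasidone) and 1284 (olanzapine). The total of 926387 calls became 1441844 (Untreated alone), 536336 (vehicles), 454649 (17 groups) and 102826 (set references), and the 360 pairs with at least 100 calls became 149 (set references). The class counts were 4911, 4823 and 3574 in brain, pituitary and liver with all libraries in the fit, and 25, 23 and 26 for aripiprazole and clozapine against CMCTween within set C, which changes both the drugs and the reference, so that these drops are not of the reference alone. Of 66 list tests, 31 passed planned by fry, against 17 with the set references, 17 with the preset and 9 with the estimated correlation. Within sets, where 17 of 66 passed by fry, 26 passed with the preset correlation. The p53 list passed in 7 tissues instead of 21 for cisplatin with the estimated correlation, and for Dox in 1 instead of 0 with the set reference and 0 of that 1 with the estimated correlation (fry adjusted p, 10 lowered in the planned comparison).

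DESeq2 gave planned counts of 1578 (Dox in heart), 1704 (Dox in bone marrow), 1732 (EMPA in liver), 1453 (alendronate), 1447 (risedronate), 2138 (teriparatide) and 1444 (lenalidomide). Within sets it gave 1038 (cisplatin in bone marrow), 29 (Dox in heart), 11 (Dox in bone marrow), 892 (APAP), 0 (risedronate, 833 genes at an unadjusted p under 0.05 by edgeR), 128 (teriparatide), 15 (lenalidomide), 13 (Repatha), 1021 (asenapine) and 641 (olanzapine). The other groups of the set as reference gave 2739 (cisplatin in bone marrow), 46 (Dox in heart), 250 (Dox in bone marrow), 30 (EMPA in kidney), 23 (EMPA in liver), 367 (teriparatide), 72 (lenalidomide), 20 (Repatha), 9 (aripiprazole) and 2 (clozapine). With no filter the within-set counts were 27 (Dox in heart), 36 (Dox in bone marrow), 51 (EMPA in kidney), 22 (EMPA in liver), 52 (alendronate), 33 (risedronate), 5 (lenalidomide), 47 (Repatha), 194 (sofosbuvir), 22 (aripiprazole) and 24 (clozapine), and 23 for alendronate minus risedronate. A fit of the set alone gave 8 (Dox in heart), 26 (Dox in bone marrow), 17 (EMPA in kidney), 2 (EMPA in liver), 4 (risedronate), 7 (lenalidomide), 11 (Repatha), 261 (sofosbuvir), 45 (aripiprazole), 34 (clozapine) and 414 (lurasidone). The replicate block gave 13 (Dox in bone marrow), 9 (EMPA in kidney), 5 (risedronate), 116 (teriparatide), 10 (lenalidomide) and 19 (clozapine) within sets and 317 (sofosbuvir) planned, and a fit of the drug and the controls alone gave 814 (sofosbuvir).

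Leaving out 1 library at a time gave the following lowest and highest counts, planned and then within the set. They were cisplatin in kidney 3409 to 5123 and 1337 to 2333, cisplatin in bone marrow 2641 to 3830 and 1042 to 1350, Dox in heart 1357 to 2555 and 4 to 7, and Dox in bone marrow 1459 to 2991 and 0 to 1. They were APAP 863 to 1533 and 627 to 1213, EMPA in kidney 3100 to 4523 and 0 to 4, EMPA in liver 1531 to 2496 and 0 to 3, and alendronate 1205 to 2328 and 0 to 72. For risedronate they were 1132 to 2250 and 0 to 19, teriparatide 1853 to 3361 and 35 to 121. Next were lenalidomide 1369 to 2421 and 1 to 16, Repatha 1372 to 2233 and 0 to 3, sofosbuvir 131 to 465 and 19 to 77. The antipsychotics had aripiprazole 2149 to 3343 and 3 to 7, asenapine 3237 to 3858 and 869 to 1633, clozapine 2569 to 3761 and 3 to 8, lurasidone 1275 to 2257 and 92 to 717, and olanzapine 1877 to 3157 and 265 to 1077. Clozapine minus olanzapine ranged from 191 to 288 and alendronate minus risedronate from 0 to 70. The planned counts that moved by more than 1.5 times did so without a library of the drug. These were Dox replicate 3 (1528) or 4 (1357) in heart and 4 (1459) in bone marrow, APAP 1 (863) or 2 (874), EMPA 1 (1578) or 2 (1531) in liver and alendronate 1 (1205). Others were risedronate 1 (1132) or 2 (1148), teriparatide 1 (2133) or 2 (1853), and lenalidomide 3 (1369) or 4 (1558). The rest were Repatha 1 (1372) or 3 (1398), sofosbuvir 1 (135) or 2 (131), aripiprazole 4 (2149), lurasidone 1 (1275) or 2 (1430) and olanzapine 1 (1877).

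Of 217 single genes followed, 206 passed within their set, and 103 of these lost the call when 1 library was left out. Of the 217, DESeq2 kept 140 on the same side of the threshold within sets, 9 lost and 1 gained a call, and the others had no adjusted p from it, among them 64 of the 206. The replicate block kept 195, no filter 209, RLE 217, and the other groups of the set 133. Planned, 191 kept their side with Untreated alone, 200 with the vehicles, 195 with the 17 groups and 193 with the set reference. Changes of sign, with the log2 value, were: with the set reference Nppa (Dox, 0.19), Snrpd1 (0.80), Fpr2 (-0.67), 2900060B14Rik (-0.98), Slain2 (-0.82), Lrrc58 (-0.70), Prnp (-0.62), S100a11 (-0.79), Car2 (-0.64) and Malat1 (aripiprazole, -0.43). With Untreated alone they were Lilr4b (0.27), Klf13 (0.11), Sost (0.0843), Ranbp1 (0.49) and Ppp1r1b (-0.0338). With the vehicles they were Car2 (-0.13), Tmem97 (0.0532), Malat1 (-0.0396) and Jun (asenapine, 0.0899), and with the 17 groups Fpr2 (-0.19), Slain2 (-0.0893), S100a11 (-0.11), Tmem97 (0.13) and Malat1 (-0.22). Within the set, against its other groups, Car2 changed (0.22). Planned values also changed sign without 1 library for Prnp (EMPA replicate 2, -0.0166, highest 0.33 without EMPA replicate 1) and Malat1 (CMCTween replicate 3, -0.00166, and aripiprazole replicate 4, -0.00255, highest 0.0493 without CMCTween replicate 4).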

Other observations

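The tests of the library sets and of depth were chosen after the result was seen, while the tests of the splits, of the colon shift and of the aripiprazole lungs were written down before theirs. Values in this part are within library sets unless said otherwise. Here too, tissues of a drug may come from the same mice. Glucocorticoid-responsive genes were raised by APAP in 21 of 24 tissues (fry adjusted p under 0.05 over 12585 tests, 11 with an estimated correlation, median of the tissue medians 1.19), by asenapine in 23 (9, median 0.88) and by cisplatin in 16 (none with an estimated correlation, median 0.70). Genes of fatty acid oxidation were raised by APAP in 18 tissues (9 with an estimated correlation) and by cisplatin in 14 (1). In the APAP kidney all 19 of them rose, with a median of 1.85, and all 13 immediate early genes rose, with a median of 3.01.

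In the thymus all 25 cell cycle genes fell with cisplatin (median -3.58, adjusted p = 7.33e-12) and with APAP (median -2.22, adjusted p = 3.49e-11), and 11 of 12 T cell genes fell with cisplatin (median -1.91). Acute phase genes were raised by cisplatin in 13 of 20 tissues (5 with an estimated correlation, median 1.74) and by sofosbuvir in 4 (1). In the cisplatin ileum 6 of 6 rose with a median of 4.79, beside 7 of 8 macrophage genes with a median of 2.14. All 8 erythroid genes fell in the cisplatin skull (median -7.81), a bone that holds marrow. The clock list was raised by asenapine in 7 of 24 tissues, none with an estimated correlation, and collection times are not in the labels.

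The treatments fell into sets in 23 of 24 tissues. Sofosbuvir in jejunum has 4 libraries, and its replicates 3 and 4 differ from its replicates 1 and 2 along the shift between sets B and A seen in the other 23 tissues (correlation 0.558 over 3168 genes, slope 0.749) and along that between sets C and A (0.488, slope 0.595), although drug and tissue are the same. This is what a technical difference between library sets, such as in library preparation or sequencing, would show, and it may be the main source of the split. Greater depth of the Untreated libraries is argued against, because Sucrose, at the depth of the others, differed from CMCTween by a median of 8.61 times as many genes as from Untreated. Effects of the drugs stay open for the part that the sofosbuvir libraries do not cover. Effects of the animals' cohort or of the season stay open throughout, since the labels do not say whether the sofosbuvir replicates share a cohort. In each set the treatments and the set cannot be told apart.

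Other splits of the same libraries into groups of the same sizes, 100 per result with the real one included, gave as many genes as the class comparison in 1 case in brain (2881 genes, highest other 2863), 3 in pituitary (2681, highest other 4715) and 2 in liver (1954, highest other 2632). For asenapine in brain, in a fit of only its 4 and the 6 control libraries, the number was 4 (625, highest other 1621). Each share is under 0.05. The splits moved libraries singly, although libraries of 1 treatment or set are alike, so the shares cannot exclude chance for whole treatments or sets. The real groups keep all 4 set A libraries together, and the 2, 1 and 3 larger splits in pituitary, liver and brain also put all 4 set A libraries in 1 group. This points to the sets as the structure of these libraries, and the shares do not part the drugs from the sets. Within set B, 1 split in 100, the real one, gave as many genes for asenapine (514, highest other 506). The set C counts for the class were 25 in brain, 23 in pituitary and 26 in liver.

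Risedronate and alendronate, which differed by no gene in skull by edgeR (688 at an unadjusted p under 0.05, 0 by DESeq2), differed by 1182 genes in bone marrow, 1040 in colon and 969 in ileum, and by 12 or fewer in each other tissue. The colon shift went with that in bone marrow (correlation 0.70 over 4848 genes) and in ileum (0.596 over 6367). If sub-sets of libraries in set B were the cause, other pairs of drugs might show the same shift in other tissues, and the difference of asenapine and lurasidone in thymus had a correlation of 0.249 with the colon shift (5339 genes). It had 0.279 with that in bone marrow and 0.239 with that in ileum, but also 0.261 in skin, where 12 or fewer genes differed, and -0.223 in thymus. The technical and the biological explanation cannot be told apart here, since the labels give no preparation batch and each tissue has 2 libraries per drug.

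In lung, aripiprazole gave 1135 calls, its highest count in 24 tissues. Its lung libraries held transcripts of 491 genes chosen for expression in testis and near absence from the other 34 lung libraries. Levels in other tissues were not used in the choice, so another source tissue was not tested. These genes stood at a summed 6116 CPM in replicate 2 and 7219 CPM in replicate 4, or 7.87 and 9.29% of the level in testis (77701 CPM). The other 34 lung libraries, low by that choice, had a mean of 94.4 CPM and at most 387. Over these genes the aripiprazole lung followed testis with a Spearman correlation of 0.890. Carry-over of testis RNA or reads is a candidate explanation, and the lung count for aripiprazole therefore cannot be read as a drug effect. Whether any mixing arose, at dissection, in the library or in sequencing, was not tested.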
